A study of Homo sapiens with 4 samples.

How the data were processed

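Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 4 libraries of the human renal carcinoma cell line 786-O. Per the labels, 2 libraries came from negative control cells that express Cas9 with a wild-type genotype (WT control) and 2 from DEK knockout cells (DEK KO). The labels say that the Cas9-expressing line was itself a clone and that knockout cells were infected with guide RNA virus and sorted as single cells. They do not say whether the 2 libraries of a group came from separate clones or cultures, so every p-value across libraries measures the spread between these samples, which may be technical. The extraction and library text in the labels describes RNA and an mRNA kit, whereas the series is described as ATAC-seq and the molecule as genomic DNA. How the ATAC libraries were made is therefore not given in the sources used here.

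Each library had 1 deposited peak list in narrowPeak format, so peaks were called per library and not on pooled samples, as the separate lists show. The submitters' processing notes name cutadapt 1.18, Bowtie2 2.2.5, SAMtools 1.7, Picard 2.26.9, deepTools 3.5.1, MACS2 2.2.7.1, DiffBind 3.6.5 and ChIPseeker 1.32.1, and the builds GRCh38 and hg38, without settings. Whether reads were shifted for the transposase is not given in the sources used here. The deposited score column followed 10 times −log10 q cut to a whole number in nearly all rows. The deposited fold column gives the ratio of pileup to background at each peak's summit, as the authors' peak caller wrote it. The deposited p and q columns are on the −log10 scale, and the last column holds the authors' summit offset in bp. The lowest deposited −log10 q was between 1.30 and 1.32 in every list, which corresponds to a q-value limit of 0.05. Fold and −log10 values belong to 1 list each and were used only to describe, rank or filter peaks within that list.

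Peaks on chromosomes 1 to 22 and X were kept, which left out between 135 and 167 peaks per list. No interval occurred more than once in a list. The 4 lists were merged wherever peaks overlapped by at least 1 bp, and each merged region was classed by the lists that called it. KO-only regions were called in both DEK KO lists and in neither control list. WT-only regions were called in both control lists and in neither DEK KO list. Mixed regions, called in exactly 1 control and 1 DEK KO list, served as the chance counterpart because they are called in the same number of lists. Within a list, each peak received a percentile of its −log10 p, and a one-genotype region was ranked by the lower of its 2 percentiles. Base overlap was given as the Jaccard index from bedtools 2.31.1. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

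Gene positions came from a RefSeq table of GRCh38.p14 with 19974 protein-coding genes on these chromosomes, and all 735 genes of the fixed lists matched it. The table gives no strand, so the planned distance to a transcription start site was replaced by the distance to either end of a protein-coding gene. A region within 1 kb of such an end is called a gene-end region, which covers starts and ends of transcription alike. A planned scan of 35 transcription factor motifs needed genome sequence and was not run. Regions were assigned to the gene with the nearest end within 50 kb.

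The 28 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists covered HIF and hypoxia targets, glycolysis, mesenchymal and epithelial genes, proximal tubule, distal nephron, AP-1, NF-kB, interferon response, MHC, cell cycle, p53 targets, DEK partners and histone chaperones, WNT, TGF-beta and BMP, growth factors, Hippo and TEAD targets, MYC and ribosome biogenesis, lipid metabolism, NRF2, HOX genes, developmental transcription factors, ribosomal proteins, and markers of neurons, blood cells, hepatocytes, and endothelium with fibroblasts. The counts of 1 further list, which entered the tests over all 28, are not reported here. The rule named DEK in every library, the 12 genes per direction with the highest-ranked gene-end region, the 6 highest-ranked other regions per direction, the 6 genes per direction with the largest surplus of one class of region, and up to 4 members of each list. Gene lists were tested with 10000 random gene sets matched on the number of assigned regions, two-sided, with Benjamini-Hochberg adjustment over the lists. Gene-end shares were compared with two-sided Fisher's exact tests over regions. The spread over chromosomes was tested with 10000 permutations of the class labels and with Fisher's exact tests per chromosome, adjusted by Benjamini-Hochberg. Regions and genes are not replicates, so these p-values describe these 4 lists. Shares carry exact 95% binomial intervals, which cover counting error only. Library values were compared with an exact permutation test over the 6 assignments of 4 libraries, whose smallest possible p is 0.333.

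Read totals are not part of a peak list. Relative depth was estimated from the lists. The commonest pair of fold and −log10 p in each list was solved for a whole pileup over a constant background, with MACS2's pseudocount of 1 in the fold. This background fitted between 23.7% and 28.7% of peaks per list within a tolerance of 0.01 pileup units and 0.01 on the −log10 scale, the others having a local background. The background was 2.16 and 2.39 in the control lists and 1.92 and 1.90 in the DEK KO lists. Divided by the smallest peak width, taken here as the fragment length, it gave relative depths of 1.05 for WT control replicate 2, 0.836 for DEK KO replicate 1 and 0.924 for DEK KO replicate 2, with WT control replicate 1 set to 1.

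The steps were tested on simulated data. With planted sites and lists of the observed lengths, 93.0% of 2000 KO-only sites and 89.3% of 1000 WT-only sites were recovered. None fell into the opposite class, but this was fixed in advance, since planted sites could not be called in the other genotype. The planted sites were also strong, so the recovery of weak or partly called sites was not tested. In 280 tests of gene lists with no list shifted, 2.14% had an unadjusted p under 0.05, and 8 of 10 runs called a growth factor list drawn at a KO-only share of 30%. Among 20 runs with no chromosome shifted, the mean number of chromosomes called was 0.05, and all 20 runs called chromosome 7 when it was drawn at 50%. The solver returned the backgrounds of 1.9 and 2.2 it was given, where every simulated peak had the same constant background. Local backgrounds, as most peaks of the real lists had, were not simulated. Alternatives covered stricter peak thresholds, lists of equal length, other rules of overlap and assignment, each library left out, and same-numbered pairs.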

Results

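The series profiled open chromatin by ATAC-seq in 786-O, a human clear cell renal carcinoma line without functional VHL, with and without DEK, a chromatin protein that binds DNA and acts as a histone chaperone. The 4 libraries were 2 WT controls, Cas9-expressing cells with intact DEK, and 2 DEK KO libraries. Each was represented by the authors' peak list on GRCh38. On chromosomes 1 to 22 and X, the lists held 89563 and 90409 peaks in WT control replicates 1 and 2, and 102760 and 99508 peaks in DEK KO replicates 1 and 2. The comparison asks where accessible regions differ between cells with and without DEK.

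The DEK gene itself (chromosome 6, 18223860 to 18264530) held 4 regions, and all 4 were called in every library. The region at its end of higher coordinate (18263024 to 18265209) had fold enrichments of 2.58 and 2.82 in WT control replicates 1 and 2 and of 3.76 and 4.99 in DEK KO replicates 1 and 2. Its percentiles within the lists were 11.9, 24.1, 39.5 and 57.6 in the same order. A knockout by small insertions or deletions leaves the gene in place, so these peaks do not check the knockout labels.

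The DEK KO lists were longer, with 101134 ± 2300 peaks (SD, n = 2) against 89986 ± 598 in the controls (n = 2), a ratio of 1.12. They were also narrower, with a median width of 572 ± 31.1 bp against 619.5 ± 13.4 bp. The share of peaks at gene ends was 13.3% ± 0.441 in DEK KO and 14.7% ± 0.0752 in the controls. The number of such peaks was not lower in DEK KO, with 13354 and 13552 in replicates 1 and 2 against 13244 and 13273 in the controls. In list length, median width and gene-end share both DEK KO libraries lay on the same side of both controls, but the exact permutation test gave p = 0.333, the smallest that 2 against 2 allows (two-sided). Covered length was 66.7 ± 4.60 Mb in DEK KO and 63.4 ± 1.84 Mb in the controls (exact permutation p = 0.667). The relative depth solved from the lists was lower in DEK KO, 0.880 ± 0.0625 against 1.03 ± 0.0363 (exact permutation p = 0.333). By this estimate, which rests on the minority of peaks with a constant background, the longer lists came from the shallower libraries.

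By bases, the control lists shared more with each other (Jaccard index 0.641) than did the DEK KO lists (0.597). The 4 pairs between genotypes had lower indices, from 0.549 to 0.580 with a mean of 0.566. The mean within genotypes exceeded the mean between them by 0.0531, the largest difference among the 3 splits of the libraries into pairs (exact permutation p = 0.333, the smallest possible). The union of the lists held 138467 regions, of which 62686 (45.3%) were called in all 4 lists.

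In the DEK KO lists alone, the highest-ranked regions away from gene ends lay nearest to KCTD16, an auxiliary subunit of GABA-B receptors, RTTN, a centrosome protein, ADD2, a membrane skeleton protein, RND3, METTL14, a subunit of the RNA adenosine methyltransferase, and DSE, an epimerase of dermatan sulfate. The region nearest KCTD16 (chromosome 5, 144697873 to 144698811) lay 212 kb from the gene, between genes, with folds of 11.1 and 13.2 in DEK KO replicates 1 and 2. The region nearest RTTN (chromosome 18, 69992707 to 69993282) lay 9.75 kb from the gene with folds of 13.2 and 15.1. The ADD2 region (chromosome 2, 70726883 to 70727773) and the DSE region (chromosome 6, 116424065 to 116424475) lay inside gene spans, 40.4 and 20.4 kb from the nearest gene end. The regions nearest RND3 (chromosome 2, 150063241 to 150063833) and METTL14 (chromosome 4, 118629390 to 118629991) lay 404 and 55.4 kb away, between genes. Their lower percentiles in the DEK KO lists ran from 85.8 to 88.1, and neither control list had a peak at any of the 6.

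At gene ends, the highest-ranked KO-only region lay by PRDM9, the methyltransferase that places meiotic recombination sites (chromosome 5, 23527339 to 23527871, lower percentile 69.7, folds 7.11 and 8.75). The next were PCOLCE, an enhancer of procollagen processing (chromosome 7, 100607125 to 100607449, lower percentile 67.2), GUCY2D, a retinal guanylate cyclase (chromosome 17, 8019438 to 8020022, 66.2), MLLT1, a reader of acylated histones (chromosome 19, 6279963 to 6280362, 65.8), and MFSD1, a lysosomal transporter (chromosome 3, 158830256 to 158830881, 63.5). Then came ATP6V0D2, a subunit of the vacuolar proton pump, the transcription factor gene ETS1 (chromosome 11, 128458325 to 128458657, 60.1), TTLL1, which modifies tubulin, PPP2R2C, a phosphatase subunit, CHRD, an antagonist of BMP signals, OSTF1 and MAP1LC3BP1, which is uncertain because its symbol names a copy of MAP1LC3B. The lower percentiles of these 12 regions ran from 55.2 to 69.7. Those at ATP6V0D2, ETS1 and PPP2R2C lay at the gene end of lower coordinate, and the others at that of higher coordinate. Strand was not given, so none of them is shown to be a promoter.

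In the control lists alone, the highest-ranked regions away from gene ends lay nearest to LDHB, a subunit of lactate dehydrogenase (chromosome 12, 21666188 to 21667570, lower percentile 81.0, folds 12.3 and 10.7), EPB41L4A, and SGK1, a kinase that controls renal sodium transport (chromosome 6, 134223460 to 134224643, 78.1, fold 11.6 in replicate 1). They were followed by NSUN4, a mitochondrial RNA methyltransferase, ADRA2A, an adrenergic receptor, and PPARGC1A, a coactivator of mitochondrial genes (chromosome 4, 23819104 to 23819717, 74.6, folds 9.18 and 9.09). The SGK1 and PPARGC1A regions lay inside gene spans, 54.2 and 27.1 kb from the nearest gene end. At gene ends, the 12 WT-only regions with the highest rank lay by LOC124900512, STEAP1B, MARCKSL1, an actin-associated protein, ACMSD, an enzyme of tryptophan breakdown, RIPOR1, ARHGEF35, PSMA3, a proteasome subunit, PHLDB1, KCNA2, a potassium channel, C11orf97, ERGIC1 and PDSS2, an enzyme of ubiquinone synthesis. Their lower percentiles ran from 41.5 to 75.5, and the highest were at LOC124900512 (chromosome 2, 96009992 to 96010585, 75.5) and STEAP1B (chromosome 7, 22500031 to 22500320, 73.0). ARHGEF35 has a near-identical neighbour, ARHGEF5, so its region is uncertain, and STEAP1B lies on the part of chromosome 7 described with the chromosomes. Without strand, the WT-only gene-end regions too may lie at the start or the end of transcription.

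In all, 8673 regions were KO-only and 3554 were WT-only, a ratio of 2.44 and a KO-only share of 70.9% (95% exact interval 70.1 to 71.7). Regions with both peaks above the 50th percentile of their lists numbered 875 among KO-only and 135 among WT-only regions, and 533 and 162 when all lists were cut to the length of the shortest. The 12227 one-genotype regions, 8.83% of the union, exceeded the regions that part the libraries in the other 2 ways, 3675 by replicate number and 3709 crossed. With 3 splits in all, no share under 0.05 can be reached. The counts depended on list length. When every list was cut to its 89563 highest-ranked peaks, 6393 regions were KO-only and 4934 WT-only, a share of 56.4% (55.5 to 57.4), and with the top 20000 peaks 1714 were KO-only and 1638 WT-only, a share of 51.1% (49.4 to 52.8). Simulated lists of the observed lengths with no genotype effect gave a KO-only share of 74.1%, with 6.17% of the union in one genotype, and 49.5% at equal lengths. Leaving out a library makes presence or absence easier to meet: KO-only regions then numbered 13012 without WT control replicate 1, 21396 without DEK KO replicate 1 and 21734 without DEK KO replicate 2, and WT-only regions 11829 and 10213 without WT control replicates 1 and 2, and 8391 and 5957 without DEK KO replicates 1 and 2.

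**Figure D1:**
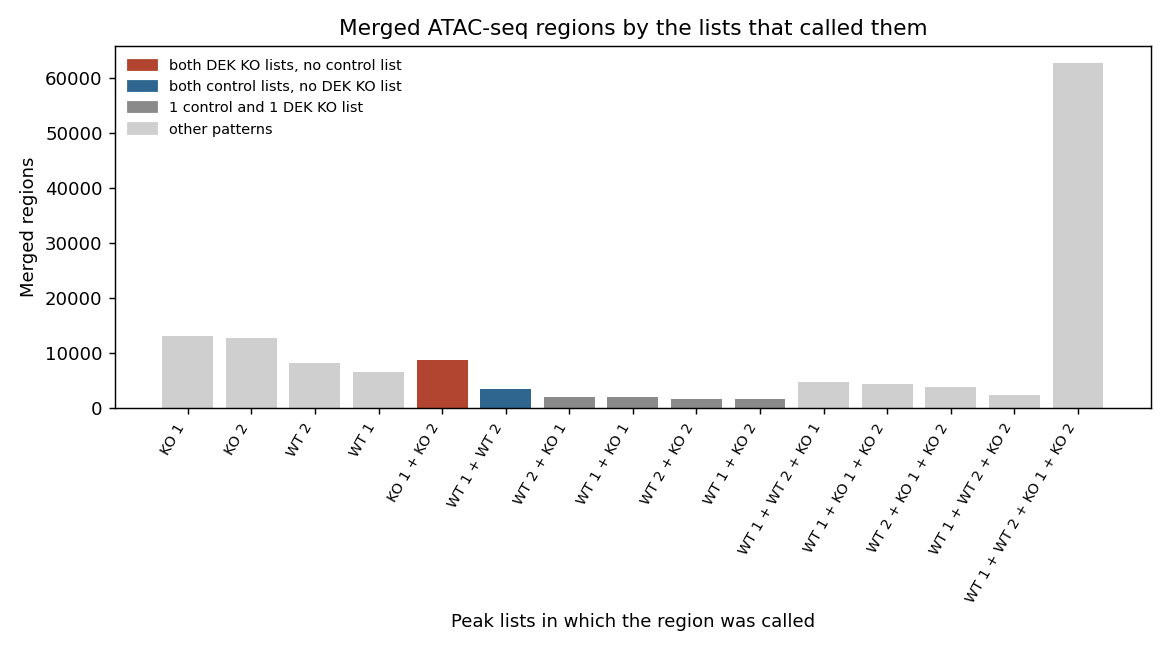
Bars give the number of merged regions for each combination of peak lists that called them (WT 1 and 2, control replicates; KO 1 and 2, DEK KO replicates). The 8673 regions called in both DEK KO lists alone outnumber the 3554 called in both control lists alone, and 62686 regions were called in all 4 lists.

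**Figure D2:**
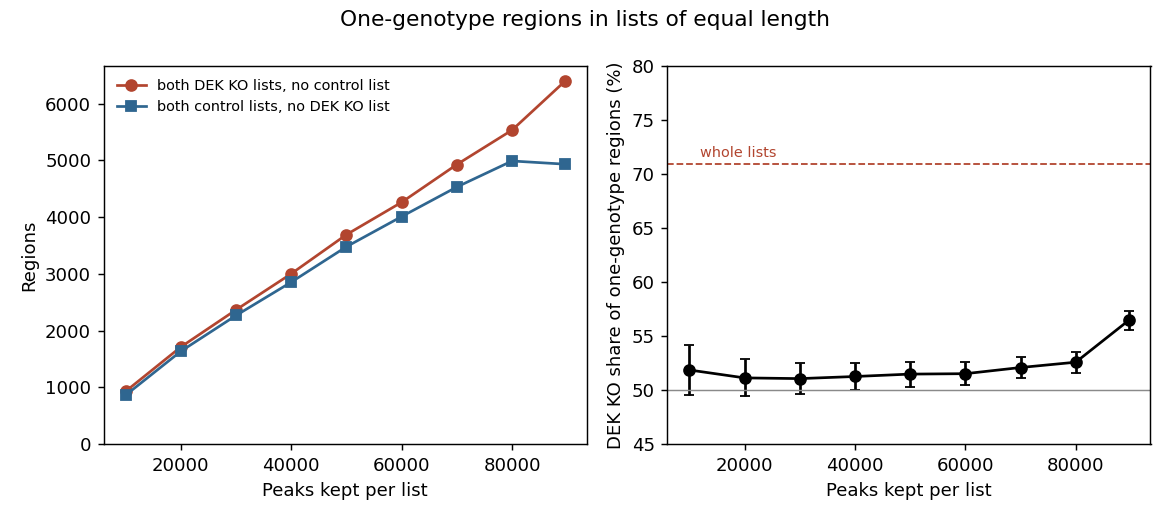
The left panel plots KO-only (circles) and WT-only (squares) regions, and the right panel the KO-only share in percent with 95% exact binomial intervals, against the number of peaks kept per list; the dashed line marks the share with whole lists (70.9%) and the grey line 50%. The share lies at 51.1% with 20000 peaks per list and at 56.4% with 89563.

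Genes with the largest surplus of KO-only regions were ADAMTS16, a secreted metalloprotease (6 KO-only and 1 WT-only), FBXL7, a ubiquitin ligase subunit (5 and 0), and MGAT5, which branches N-glycans (5 and 0). ASAP1, a regulator of ARF GTPases, BPIFB4 and CCNE1, the cyclin of entry into DNA replication, had 4 KO-only and 0 WT-only regions each. The largest surplus of WT-only regions was at LCLAT1, an acyltransferase of cardiolipin (0 KO-only and 5 WT-only), and ZNRF2, a ubiquitin ligase (0 and 5). HS6ST1, a heparan sulfate sulfotransferase, SPART and UNC13C, a synaptic vesicle protein, had 0 KO-only and 4 WT-only regions, and ANKRD33B had 1 and 4. Many genes tied at the last place, since 20 genes reached the surplus of CCNE1 and 21 that of ANKRD33B.

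Gene-end regions were rarer among KO-only regions than among WT-only regions. They made up 337 of 8673 KO-only regions (3.89%, 95% exact interval 3.49 to 4.31) and 214 of 3554 WT-only regions (6.02%, 5.26 to 6.85), an odds ratio of 0.631 (Fisher's exact test, two-sided, p = 5.36e-07, adjusted 8.04e-07 over 3 comparisons). Mixed regions had 486 of 7384 (6.58%), so that by Fisher's exact test KO-only regions differed from them (odds ratio 0.574, adjusted p = 4.48e-14) and WT-only regions did not pass the test (odds ratio 0.909, adjusted p = 0.278). Regions called in all 4 lists lay at gene ends in 18.5% of cases. Regions inside a gene span but away from its ends made up 44.3% of KO-only and 53.3% of WT-only regions. In terms of genes, 366 had a KO-only and 226 a WT-only gene-end region, 6 had both, and 11986 had a region called in all 4 lists. Leaving out a library changed the size of the difference of -2.14 percentage points: it was -0.515 without WT control replicate 1 (Fisher's exact p = 0.0656, no longer past the threshold), -0.634 without DEK KO replicate 1 (p = 0.0196), -1.20 without WT control replicate 2 and -3.55 without DEK KO replicate 2.

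Among the gene lists tied to this tumour, HIF and hypoxia targets had 13 KO-only and 6 WT-only regions. PFKFB3, a regulator of glycolysis, had 2 of each class, CCND1, a cyclin, had 2 KO-only and 0 WT-only, and STC2 had 0 and 2. ANGPTL4, a lipase inhibitor, had 1 KO-only region and a KO-only call at a gene end. Glycolysis enzymes had 4 KO-only and 3 WT-only regions, and PKM, the pyruvate kinase gene, had a KO-only region at its end that was assigned to a neighbour. Proximal tubule genes, which mark the segment from which such tumours arise, had 13 and 5: MME, the neprilysin gene, had 0 KO-only and 3 WT-only, CUBN, the endocytic receptor cubilin, had 3 and 1, and GGT1 and SLC13A3 had 2 and 0. Distal nephron and collecting duct genes had 9 and 2, with 2 KO-only and 0 WT-only at PVALB and at the sodium channel gene SCNN1G.

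Mesenchymal genes had 15 KO-only and 3 WT-only regions, among them 3 and 0 at CD44, a hyaluronan receptor, and 2 and 0 at SNAI2, a repressor of epithelial genes. Epithelial junction and keratin genes had 6 and 1, with 2 and 0 at TJP1. Hippo and TEAD targets had 18 and 5, with 4 and 0 at ASAP1 and 3 and 0 at WWTR1, and KO-only gene-end regions at CCN1 and AMOTL1. HOX genes had 1 and 2, the KO-only region lying at HOXA11 and the WT-only regions at HOXC10 and HOXA4. Developmental transcription factors had 22 and 6, including 3 and 0 at TBX5.

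Growth factor receptors and ligands had 22 KO-only and 15 WT-only regions, with 3 and 0 at HGF, the ligand of MET, and 0 and 3 at FGFR2. WNT pathway genes had 17 and 5, with 3 and 0 at NKD1, and TGF-beta and BMP pathway genes had 15 and 7, with 3 and 0 at SMAD7 and 0 and 2 at TGFBR1 and ID4. AP-1 family genes had 2 and 4, of which 3 WT-only regions were at FOSL2. NF-kB and inflammatory genes had 7 and 2, with KO-only gene-end regions at CCL5 and IL1B. Interferon response genes had 11 and 1, with 11 of 28 members holding more KO-only regions, IFIT2 among them, but their KO-only share of 91.7% fell to 53.8% with lists of equal length and to 66.7% with −log10 q of at least 5. MHC and antigen presentation genes had 2 and 2.

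DEK partners and histone chaperones had 8 KO-only and 0 WT-only regions, including 2 at PARP1 and at TFAP2A and a gene-end region at NASP, a chaperone of linker and core histones. Their KO-only share of 100% fell to 42.9% with −log10 q of at least 5, to 80% with lists of equal length, and to 60% and 61.5% without WT control replicates 1 and 2. The share over all genes also moved, to 65.0%, 55.2%, 52.0% and 54.5% in the same order. Cell cycle and replication genes had 10 and 3, p53 targets 6 and 3 with 3 and 0 at ZMAT3, MYC and ribosome biogenesis genes 5 and 3, lipid and sterol genes 11 and 4 with a KO-only gene-end region at SREBF2, and NRF2 genes 1 and 1. Ribosomal protein genes had 2 and 2. Markers of other cell types also held one-genotype regions, with 13 and 3 for neuronal genes, 6 and 2 for blood cell markers, 5 and 1 for hepatocyte markers, and 7 and 2 for endothelial and fibroblast markers. WT-only gene-end regions among the named members of the lists lay at PDGFRB, HLA-DMA, LGR5, VEGFC, ODC1, HOXC10, TBX15 and APOB. Their lower percentiles were 0.804, 31.1, 1.09, 11.8, 0.781, 22.7, 10.2 and 8.20 in the same order. Those at PDGFRB, LGR5 and ODC1 thus lay near the calling limit. KO-only gene-end regions of the named members were also weak, from 2.52 at IFIT2 to 34.0 at NASP. Among the lowest were 2.86 at SLC17A7, a neuronal gene, 4.18 at RPS18, a ribosomal protein gene, and 6.22 at AMOTL1.

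None of the 28 lists passed the test against random gene sets, where the KO-only share over all genes was 69.9% (permutation test over genes, two-sided). The count past an adjusted p of 0.05 was 0, and at an unadjusted p under 0.05 it was also 0. The smallest p was 0.0856, for HOX genes, and the smallest adjusted p was 0.803. The lists held between 2 and 37 one-genotype regions each, and in simulated data a shift of the growth factor list to a KO-only share of 30% was called in 8 of 10 runs. That list held the most regions, so the simulation does not give the power for the smaller lists or for smaller shifts.

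One-genotype regions were unevenly spread over the chromosomes (chi-square 178, permutation p = 0.0001, the smallest that 10000 permutations can give). The KO-only share was lower on chromosomes 1 (58.9%, 95% exact interval 56.0 to 61.9, adjusted p = 2.14e-17) and 7 (65.6%, 62.1 to 69.0, adjusted p = 0.00447) than elsewhere, by Fisher's exact test. It was higher on chromosomes 16 (80.9%), 17 (80.3%), 19 (82.0%) and 22 (83.9%), with adjusted p of 3.02e-05, 3.52e-05, 0.000121 and 3.52e-05. The other 17 of the 23 chromosomes did not pass the test. GGT1, PVALB, SREBF2 and TTLL1, named above with KO-only regions, lie on chromosome 22, where the share was high throughout.

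Among 10 Mb bins of chromosome 7 with at least 20 one-genotype regions, those of the first 40 Mb had the lowest KO-only shares, between 35.2% and 41.2%. From 40 to 60 Mb the share was 56.9% (43.2 to 69.8), also below the genome share of 70.9%, with 31 KO-only and 19 WT-only regions from 40 to 50 Mb (62.0%, 47.2 to 75.3) and only 2 and 6 from 50 to 60 Mb. The first 60 Mb, which hold STEAP1B and ZNRF2, were pooled as a segment after their values were seen. There, 96 regions were KO-only and 129 WT-only (42.7%, 36.1 to 49.4), against 394 and 128 (75.5%) on the rest of the chromosome and 71.5% over the genome outside the segment. Among 1310 regions of the segment called in all 4 lists, the median rank by −log10 p among all such regions was 53.9 and 54.0 in WT control replicates 1 and 2 and 44.0 and 46.7 in DEK KO replicates 1 and 2. The share on the segment stayed below that elsewhere in each of 11 alternatives. It was 55.0% against 72.2% elsewhere without DEK KO replicate 1, the smallest difference.

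**Figure D3:**
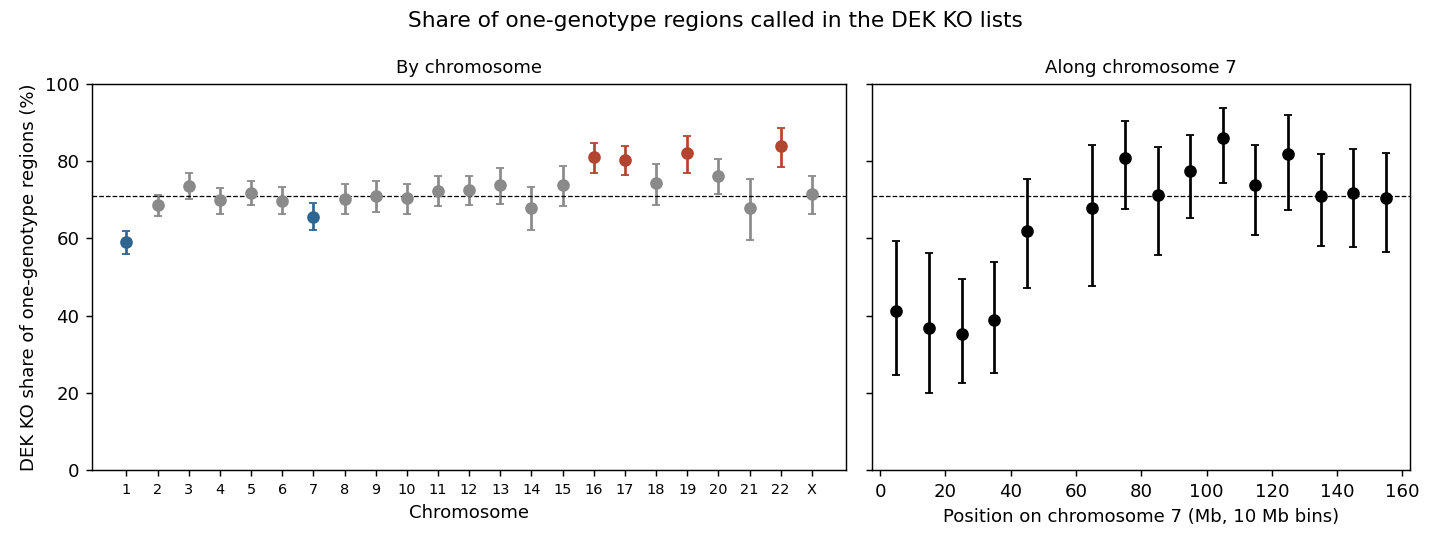
Points give the KO-only share of one-genotype regions in percent by chromosome (left; red and blue mark chromosomes above and below the rest at an adjusted p under 0.05) and in 10 Mb bins with at least 20 such regions along chromosome 7 (right), with 95% exact binomial intervals; the dashed line is the genome share of 70.9%. The bins of the first 40 Mb of chromosome 7 lie between 35.2% and 41.2%, and the bin from 40 to 50 Mb at 62.0%.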

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

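The KO-only share of one-genotype regions stayed above 50% under every alternative tried, but its size followed the lists. It was 65.3% with −log10 q of at least 5 and 62.5% with at least 10 (4964 KO-only regions), 56.4% with lists as long as the shortest, and 51.1% with the top 20000 peaks (1714 KO-only and 1638 WT-only regions), where its interval of 49.4 to 52.8 holds 50%. Summit windows of 500 bp gave 69.0%, absence within 1 kb gave 72.0%, and 50% reciprocal overlap gave 63.5% with 5602 WT-only regions. Leaving out 1 library gave shares from 52.4% to 78.5%, KO-only counts from 12546 to 21734 and WT-only counts from 5957 to 11829, part of which follows from having 1 list fewer to meet. The counts showed no pairing of the libraries by replicate number, since same-numbered pairs shared 3675 regions that the other pair lacked and crossed pairs 3709. Whether same-numbered libraries were prepared together is not given in the labels. With the replicate block, as a mean over same-numbered pairs, there were 27525.5 KO-only and 16495.5 WT-only regions (62.5%). This count needs 1 list of each genotype, which explains its size. The difference in list length was 5644 peaks with −log10 q of at least 5 and 3716 with at least 10. With lists of equal length, 533 KO-only and 162 WT-only regions had both peaks above the 50th percentile. The lower gene-end share of KO-only regions kept its direction in the 8 alternatives run, with leave-one-out differences from -3.55 to -0.515 points. Without WT control replicate 1 it no longer passed Fisher's exact test (p = 0.0656), and the cause was not tested. Of the 18 named KO-only and 18 named WT-only regions, all were kept at −log10 q of at least 10 and in lists as long as the shortest, and 6 and 3 with the top 20000 peaks. Such cuts only remove peaks and cannot bring in a peak of the other genotype. Since the regions were named for their high rank, being kept there is no independent support. With no peak of the other genotype allowed within 1 kb 17 and 14 were kept, and with a fold of at least 5 it was 15 and 13. No gene list passed an adjusted p of 0.05 in any of the alternatives tried, where the smallest adjusted p ranged from 0.0616 to 0.865. From 6 chromosomes past the threshold the number changed to 8 with either alternative. A fold filter of 5, the equal-length percentiles and the removal of chromosomes or of the chromosome 7 segment were chosen after the data had been seen. The alternatives for motifs, like the motif scan, were not run. Read totals were not used, so the depth limits which weak peaks can be compared.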

Other observations

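The family of genes whose symbols begin with ZNF, mostly zinc finger transcription factors, was the only one of 91 symbol families of at least 20 genes whose KO-only share passed the adjusted threshold, in a test chosen after the data had been seen. It had 93 KO-only and 11 WT-only regions (89.4%, 95% exact interval 81.9 to 94.6) against 69.9% over all genes, with a permutation p of 0.0002, the smallest that the draws can give, and an adjusted p of 0.0182. In the same test 4 families had an unadjusted p under 0.05. Besides ZNF these were SLC, with a higher share (78.3%), and KLHL (33.3%) and ZBTB (41.7%), with lower ones. ZBTB, another zinc finger family, had 5 KO-only and 7 WT-only regions. Outside chromosome 19, where many ZNF genes lie in clusters, 65 regions were KO-only and 9 WT-only (87.8%), and gene sets drawn within the same chromosomes averaged 68.7% (permutation p = 0.0002). On chromosome 19, 28 were KO-only and 2 WT-only (93.3%) against a mean of 81.8% in such draws, which did not pass the test (permutation p = 0.087). ZNF429, with 3 KO-only and 0 WT-only regions, and ZNF91, ZNF536, ZNF337, ZNF664 and ZNF81, with 2 and 0 each, held the most, and ZNF124 held 0 and 2. Under 6 alternatives its share stayed above that over all genes, but it passed the adjusted threshold in 0 of them. The adjusted permutation p was 0.094 without DEK KO replicate 2 (85.5% against 76.4%) and at least 0.273 in the others, among them lists of equal length (65.3% against 55.2%). Clustered zinc finger genes are near-identical in parts, so their regions are uncertain where reads map to several copies.

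Among regions with both peaks above the 50th percentile of their lists, those nearest C8orf34 and RBFOX1, a splicing regulator, numbered 4 KO-only and 0 WT-only each. NR3C1, the glucocorticoid receptor gene, PCDH7, a protocadherin gene, GSDMC and TOX2 had 3 and 0 each. FGFR2, METTL9 and USP6NL had 0 and 2. These genes were named after their values were seen. Of the 1714 regions called only in DEK KO among the top 20000 peaks of each list, 1656 had a weaker peak in both control lists cut to 89563 peaks and 13 had none in either. Of the 1638 called only in the controls, 1590 had a weaker peak in both DEK KO lists and 4 had none. The DEK KO lists differed from each other on the first 10 Mb of chromosome 7, where the median rank of regions called in all 4 lists was 40.8 in replicate 1 and 54.6 in replicate 2, against 54.4 and 55.5 in the controls. The median rank shift of such regions, DEK KO minus WT control, was 6.11 on chromosome 22 and -3.44 on chromosome 1. The KO-only share was likewise high on chromosome 22 (83.9%) and low on chromosome 1 (58.9%). Whether copy number differed on these chromosomes was not tested.

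In the weighing that follows, the tests of depth, of other splits at equal length by peak percentile, of rank shifts on parts of the segment and of strata of peak strength, and the removal of chromosomes, were chosen only after the results were seen. The surplus of KO-only regions could come from the longer DEK KO lists. For regions with both peaks above the 50th percentile this is argued against, since with lists of equal length 533 were KO-only and 162 WT-only (76.7%, 95% exact interval 73.4 to 79.8), against 47.2% in the split by replicate number and 38.5% in the crossed split (Fisher's exact p = 0.00236 and 0.0186, each taken on its larger side). With the top 20000 peaks, all of them strong, the share was 51.1% over all regions (56.2% in the split by replicate number). Nearly all of these regions had a weaker peak in the other genotype. Above the middle of the cut lists 193 were KO-only and 95 WT-only (67.0%, 61.3 to 72.4), where the other splits had 1 region each. In the whole lists, lower percentiles of one-genotype regions reached only 88.1 (KO-only) and 81.0 (WT-only). Regions ranked above the middle of the cut lists therefore had a peak in at least 1 whole list of the other genotype. Their counts show differences in rank and not sites called in 1 genotype alone. For regions with a peak below the 50th percentile the share at the length of the shortest list was 55.1%, against 46.8% and 51.4% (Fisher's exact p = 0.0545 and 0.000231), so list length and more open sites without DEK cannot be told apart. The knockout cells were sorted as single cells, so for stronger and weaker regions alike differences between clones cannot be told apart from loss of DEK. Deeper sequencing of the DEK KO libraries is argued against by a depth ratio of 0.858, taking the smallest peak width as the fragment length, with both DEK KO libraries below both controls.

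The low KO-only share on the first 60 Mb of chromosome 7 has as a candidate explanation, from 10 to 60 Mb, a lower copy number in both DEK KO libraries, whose cells were grown from single sorted cells. From 10 to 40 Mb the share was 36.8% (28.6 to 45.6), and the median rank shift of regions called in all 4 lists was -6.76 (-7.06 and -7.18 in DEK KO replicates 1 and 2), below each of 254 overlapping windows of 30 Mb on other chromosomes (-5.36 to 6.38). From 40 to 60 Mb the shift was -8.28, below each of 267 windows of 20 Mb, and the share of 56.9% (43.2 to 69.8) was below the 71.5% outside the segment, though less low than from 10 to 40 Mb and, from 40 to 50 Mb alone, with an interval up to 75.3%. On the first 10 Mb, with a share of 41.2%, a lower copy number in both libraries is argued against by a shift of 0.554 (95% bootstrap interval -1.36 to 2.13) in replicate 2, against -9.35 in replicate 1. With the top 20000 peaks the share on the segment was 15.9% against 52.3% elsewhere, so a lower share was also seen among strong peaks. Over the genome, nearly all one-genotype regions at that cut had a weaker peak in the other genotype. The cut therefore shows a difference in rank. It cannot decide whether the share in the whole lists rests on weak peaks near the calling threshold. An effect of DEK loss was not tested and copy number was not measured.

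A difference in peak strength could account for the fewer gene-end regions among KO-only than WT-only regions. Stratified by within-list percentile, the odds ratio was still 0.682 (95% interval 0.571 to 0.815), which argues against it as the whole cause. The difference was -2.19 points without chromosomes 1, 7, 16, 17, 19 and 22, and -2.82 points with lists of equal length, which argues in the same way against uneven chromosomes and list length. A genotype effect stays a hypothesis, since regions are not replicates and differences between clones cannot be told apart from genotype. The difference without WT control replicate 1 was also only -0.515 points and did not pass the test.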
